A study of Mus musculus with 3 samples.

How the data were processed

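Cells of the anterior palatal shelves of wildtype C57BL/6J mouse embryos at E13.5 were loaded as 3 libraries, with Chromium 3' chemistry of version 3.1 per the labels' protocols. The deposited matrices hold UMI counts for 27998 genes per cell barcode. The authors' alignment used Cell Ranger 6.0.1 per the file headers, while the submitters' processing notes name Cell Ranger 2.1.1 and Seurat 4.0.4 with genome build mm10, and which version made the matrices is not settled by the files. Every value tested was a whole count, and no barcode held fewer than 500 UMIs, so some barcode filter had been applied before deposit. Medians of 9513, 10296 and 9462 UMIs per barcode in replicates 1, 2 and 3 mean that a gene without a UMI in a cell may still be active there. The labels do not say whether the libraries are separate animals, litters or pools. The p-values therefore reach no further than these 3 libraries. With the library as a block, they weigh a difference between classes against a spread that edgeR estimates partly from all genes together. A low p-value alone does not show that a gene differed evenly across the libraries. All 3 belong to 1 group, so no contrast between groups of animals exists.

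The comparisons, tests, 14 gene lists (603 genes), cell type markers, alternatives and the rule for named genes were fixed before the data were examined. A published study of this tissue and stage, in which Shox2 and Osr2 were discussed, came to mind during the design. Its values were not used, but the choice of the Shox2 and Osr2 comparisons and of some list genes may not be blind to it. Cells with at least 500 detected genes and at most 10.0% mitochondrial UMIs were kept, which left 24244 of 25020 barcodes (8689, 7817 and 7738 in replicates 1, 2 and 3). Doublets were scored with Scrublet in scanpy 1.11.5 for each library. Its automatic threshold was used where it called at least 0.5% of the cells, which held for replicate 1 only (142 cells, 1.63%), since it called 1 cell (0.013%) in each of the others. In replicates 2 and 3 the highest-scoring share given by 0.8% per 1000 barcodes was removed instead (502 cells, 6.42%, and 493 cells, 6.37%). Removing that share in every library is an alternative that was added after seeing the data, and so is the cycling comparison without the cycling cluster led by Tfap2b.

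Every count was split at random into 2 parts (binomial, probability 0.5, seed 1), with 1 part for clustering, naming and detection and the other for all tests. Clustering used the log of counts per 10000, 2000 highly variable genes without the list genes and without mitochondrial, ribosomal protein, haemoglobin and sex-linked genes, centring within each library, 30 principal components, 20 neighbours and the Leiden method at resolution 1.0 (igraph 0.11.9, leidenalg 0.10.2), which gave 25 clusters. Mesenchyme-like cells were clustered again at resolution 0.5 with 20 principal components, without cell cycle genes as features and with S and G2/M scores (43 and 56 genes) regressed out, which gave 11 clusters numbered by size.

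Clusters were named from 149 marker genes of 15 cell types. The markers were fixed in advance, but the way of applying them was revised after the clusters had been seen. A first version compared each cluster with all other cells, and a second asked for a larger excess over the median cluster. Both gave an erythroid name to clusters with free haemoglobin RNA under at least 1 setting, and the first named the shallow cluster 12 mesenchyme-like. In the version used, a class other than mesenchyme needed a median marker level at least 2-fold above the median cluster, at least 3 markers at that level and mesenchymal markers at least 2-fold below the median cluster. The erythroid name also needed haemoglobin genes at 5.0% of the UMIs or more. A cluster stayed without a name where fewer than 3 markers reached 2-fold, or where markers of another class were more frequent among its 10.0 leading genes. A cluster whose median UMI count was far under that of its libraries had to meet 1 more condition. At least 1 of its 10.0 genes with the highest ratio to all other cells had to be a marker of the class in question. Cluster 24 failed this for mesenchyme, although endothelial genes (Cdh5, Flt1, Pecam1) were among those 10.0 genes. Mesenchyme-like clusters with at least 3 cycling markers at 2-fold are called cycling-like. No list gene was a naming marker or a cell cycle gene.

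For each comparison the tested counts were summed per library and class (at least 10.0 cells), and fitted with edgeR 4.0.16 on R 4.3.3: filterByExpr, TMM, and the quasi-likelihood F test with the library as a block. Both classes of a comparison come from the same library, so the replicate number pairs them. Genes were called at an adjusted p under 0.05 (Benjamini-Hochberg over all tested genes), and list members were also adjusted over the list alone. The 18 comparisons cover 4 classes against mesenchyme-like cells, cycling-like against other mesenchyme-like cells, 11 mesenchymal clusters each against the rest, and mesenchyme-like cells with against those without a UMI of Shox2 or Osr2. Cell cycle genes were left out of the cycling comparison, and Shox2 and Osr2 out of their own. Erythroid-like cells and cells without a class name entered no test. Lists were also tested with camera from limma 3.58.1, with correlations of 0.01 and as estimated. Clusters and their tests come from the same cells, so counts over all genes include genes that formed the clusters, and the list genes are the results.

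The rule for named genes takes up to 4 members of each list with the largest changes among calls of the same sign in all 3 libraries. Over all genes it takes the 8 highest and 8 lowest (4 lowest for mesenchymal clusters) with at least 50.0 CPM, without markers. It adds 18 fixed patterning and signalling genes wherever they fit the account. Not all selected genes are printed, and some, with a depth test on 1 of them, are not reported here. Among the selected genes, those whose calls held under the alternatives were preferred after these had been run. Pairs of 25 patterning genes were scored in mesenchyme-like cells thinned to 4000 UMIs, as the log2 odds ratio of co-detection per library with 0.5 added to each cell of the table, where at least 5.0 co-detections were expected in every library. Gene positions come from the GENCODE M21 annotation of GRCm38.

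The fit was tested on simulated counts with the depth and fitted spread of the real sums and 200 changed genes, all at 10.0 CPM or more. The fitted spread was that of the trend over genes, both classes shared 1 mean profile, and as many genes rose as fell. The real comparisons called far more genes, so the rates of recovery and of false calls need not carry over to them. For epithelium-like cells (13720 genes) it recovered 100 of 100 genes changed 2-fold and 95 of 100 changed 1.5-fold, and called 4 unchanged genes. For Schwann-like cells (12927 genes) it recovered 41 and 10.0 of 100, with 6 unchanged genes called. For mesenchymal cluster 9 (13179 genes) the numbers were 95 and 63 with 5, and for the division by Shox2 (13208 genes) 100 and 100 with 8. By these rates, changes under 2-fold in Schwann-like cells are mostly out of reach.

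The alternatives were DESeq2 1.42.0, scaling by library size alone, no filter on low counts, no library block, leaving out each replicate, all UMIs for both clustering and tests, stricter filtering (at least 1500 genes and at most 5.0% mitochondrial UMIs), other doublet handling, list genes among the features, no centring, resolutions of 0.5 and 2.0 (0.25 and 1.0 for the mesenchyme), and cell cycle scores left in. The Shox2 and Osr2 divisions were repeated on cells thinned to 2000 UMIs, on cells called G1 and with sums per mesenchymal cluster. Clusters were matched between settings by shared cells, with a Jaccard index of at least 0.3, and the lowest index among the matches was 0.323. A share or a mean odds ratio counts as moved when an alternative changed it by at least 1 SD between libraries, and a number of called genes or of pairs when it changed by more than 1.5 times. No match was found for 4 mesenchymal clusters at a resolution of 0.25, for 2 with stricter filtering and for 1 under each of 6 other settings, and these enter no count of stability. Tables were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19 and matplotlib 3.10.9.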

Results

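The secondary palate, which becomes the roof of the mouth, grows from paired shelves of neural crest derived mesenchyme covered by epithelium, and stage E13.5 lies shortly before the shelves rise above the tongue. The series profiled the anterior part of these shelves in wildtype C57BL/6J mice, with the stated purpose of describing the cell populations of the tissue and the heterogeneity of its mesenchyme. Single-cell RNA was captured in droplets with the Chromium 3' chemistry of version 3.1, in which each captured molecule carries a unique molecular identifier (UMI). The 3 libraries form 1 group, so every comparison sets cell classes or clusters against each other inside the same libraries.

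Replicates 1, 2 and 3 held 9026, 8025 and 7969 cell barcodes, with 97381803, 91181163 and 86704140 UMIs in all. A barcode carried a median of 9513, 10296 and 9462 UMIs in replicates 1, 2 and 3 and a median of 3289, 3348 and 3149 detected genes. Mitochondrial genes took a median of 4.92%, 4.85% and 5.06% of the UMIs. After filtering and doublet removal, 8547, 7315 and 7245 cells remained. Every pair of libraries differed by more than sampling noise over the mesenchyme-like cells (chi-square per gene of 45.0, 47.6 and 15.1), so none is a copy of another, which does not show that they come from separate animals.

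Mesenchyme-like cells made up 82.3% ± 2.72 of the cells (SD, n = 3 libraries) and epithelium-like cells 10.4% ± 1.87. Endothelium-like cells took 1.23% ± 0.285 (288 cells), immune-like cells 0.608% ± 0.173 (143 cells), erythroid-like cells 0.58% ± 0.126 (134 cells) and Schwann-like cells 0.345% ± 0.105 (81 cells). In erythroid-like cells the haemoglobin genes took 78.1% ± 2.9 of the UMIs, against 0.0379% ± 0.0213 in mesenchyme-like and 0.825% ± 1.37 in immune-like cells. The remaining 4.55% ± 2.0 of the cells received no class name, at 5.42%, 5.97% and 2.26% in replicates 1, 2 and 3. Cells in mesenchyme-like clusters with at least 3 cycling markers at 2-fold, called cycling-like, were 23.7% ± 1.85 of the mesenchyme. With a stricter cell filter, epithelium-like cells fell to 7.92%, cells without a name to 0.123% and erythroid-like cells to 0, while cycling-like cells took 31.7% of the mesenchyme.

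**Figure D1:**
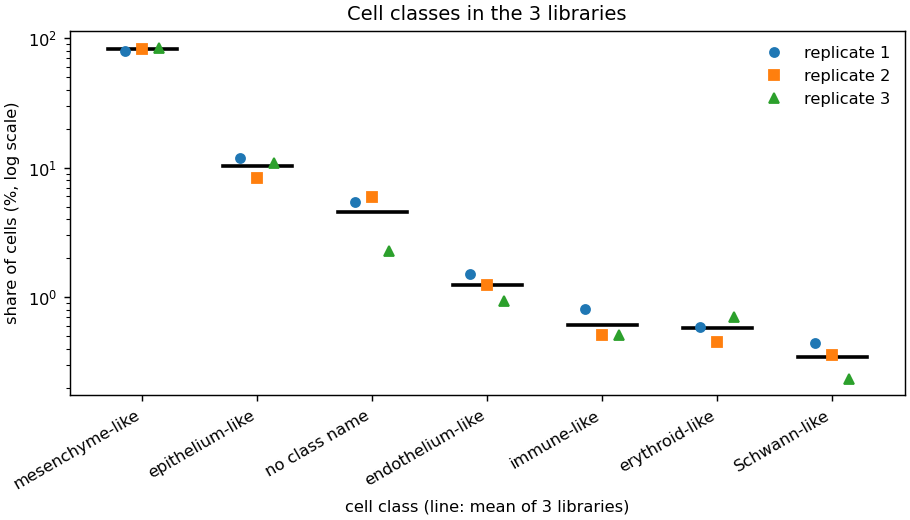
Share of each cell class among the cells kept, in percent on a log axis, with 1 point per library and the mean of the 3 libraries as a line. Mesenchyme-like cells lie between 79.3% and 84.5% and the other named classes between 0.235% and 11.97%.

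Fold changes below are log2 values from edgeR's quasi-likelihood fit with the library as a block. The ± SE after a fold change is the value implied by its F statistic, since the test itself returns no SE. This SE is approximate and can be too small, above all where a class holds few UMIs. Rxrg and Scn7a, for example, had 1 tested UMI each in mesenchyme-like cells, and Dlx5 and Dlx1 had 2 each in mesenchymal cluster 7. Levels are mean CPM (UMIs of a gene scaled to the same total) ± SD over the 3 libraries. A gene called higher or lower passed the Benjamini-Hochberg adjustment over all genes tested in its comparison. The text names 265 values of genes in these comparisons, of which 241 passed with an adjusted p of at most 0.000508, each moving the same way in 3 of 3 libraries. Genes were picked for naming from those the fixed rule selects, with preference for calls that held under the alternatives, so they are steadier than the rest of the selected genes. Where a gene had 0 UMIs in one class, only a bound is given, from a floor of 3 counts over the group. Coordinates are those of GRCm38. Camera, a competitive test of gene lists, called 100 of 252 combinations of list and comparison with its preset correlation of 0.01 and 0 with an estimated correlation, where the lowest adjusted p was 0.192, so lists are described by counts of their members.

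Epithelium-like cells carried more RNA of several ligand genes. Shh (ENSMUSG00000002633, chromosome 5, 28456815 to 28467256, minus strand), the hedgehog ligand of the oral epithelium, stood 7.90 ± 0.15 above mesenchyme-like cells (80.7 ± 6.91 against 0.323 ± 0.153 CPM). Fgf9, a growth factor that acts on mesenchyme, was 6.81 ± 0.12 higher (172 ± 10.6 against 1.51 ± 0.552 CPM), Wnt6 6.91 ± 0.16 higher (52.2 ± 8.60 against 0.422 ± 0.199 CPM), and Pdgfa, ligand of the receptor Pdgfra, 5.27 ± 0.08 higher (435 ± 12.4 against 11.3 ± 1.33 CPM). Fgf20 and Fgf8 had 0 UMIs in mesenchyme-like cells and were at least 178-fold and 51.4-fold higher. Of the patterning regulators, Sox2 (8.27 ± 0.23), Isl1 (8.51 ± 0.13) and Grhl2 (7.58 ± 0.17), an epithelial transcription factor, led the epithelium.

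Mesenchymal regulators went the other way. Shox2 (ENSMUSG00000027833, chromosome 3, 66971727 to 66981771, minus strand), a homeobox gene of the anterior palate, was lower in the epithelium at -5.00 ± 0.07 (21.2 ± 2.91 against 679.9 ± 18.3 CPM), Msx1 at -4.76 ± 0.10, Osr2 at -4.23 ± 0.11 and Foxf1 at -4.80 ± 0.15. The signals Bmp4 (-3.14 ± 0.13) and Wnt5a (-3.78 ± 0.13) were lower as well, while Pax9 fell by less (-1.30 ± 0.09) and Barx1 differed by -0.15 ± 0.18, with an edgeR adjusted p of 0.504, and was called higher without replicate 1 (0.25 ± 0.07). Ptch1, receptor and target of hedgehog signalling, was lower (-0.91 ± 0.05), and its fellow target Gli1 was not called at -0.16 ± 0.10 (edgeR adjusted p = 0.177). Tbx22 had 0 UMIs in epithelium-like cells and was at least 15.6-fold lower. Shox2 UMIs appeared in 80.2% ± 3.68 of mesenchyme-like cells (median 9663 UMIs) and in 10.1% ± 2.16 of epithelium-like cells (median 12342). Background RNA was not measured, so a Shox2 UMI in an epithelium-like cell need not mean expression there.

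Of the 57 measured palate patterning transcription factors, 15 were higher, 38 lower and 4 not called (15 and 38 adjusted over the list alone). Among 18 measured hedgehog genes, 3 were higher, 11 lower and 4 not called (3 and 11 adjusted over the list alone), and among 32 measured BMP pathway genes, 7 were higher, 22 lower and 3 not called (7 and 22 adjusted over the list alone). Fgfbp1, which releases FGFs from the matrix, was 8.87 ± 0.31 higher among 30 measured FGF pathway genes (13 higher, 12 lower, 5 not called, with 14 and 12 adjusted over the list alone). Of 53 measured WNT pathway genes, 19 were higher, 27 lower and 7 not called (19 and 28 adjusted over the list alone). Of 15 measured Notch pathway genes, 9 were higher, 4 lower and 2 not called (9 and 4 adjusted over the list alone), with Jag2 at 5.98 ± 0.22. Of 29 measured TGF-beta pathway genes, 11 were higher, 12 lower and 6 not called (11 and 12 adjusted over the list alone). Matrix genes parted by compartment among 82 measured extracellular matrix genes (22 higher, 55 lower, 5 not called, with 22 and 55 adjusted over the list alone): the laminin chain Lama5 (6.83 ± 0.15) and the hemidesmosomal collagen Col17a1 (6.48 ± 0.11) were higher, and Aspn (-5.25 ± 0.16) and Ogn (-5.47 ± 0.22), small leucine-rich proteoglycans, lower. Of the retinoic acid genes, Cyp26a1, the degrading enzyme, was higher (6.59 ± 0.23) and the binding protein gene Crabp1 lower (-4.91 ± 0.07), among 18 measured retinoic acid pathway genes (4 higher, 10 lower, 4 not called, with 4 and 10 adjusted over the list alone). Gjb2, a gap junction gene, was 8.29 ± 0.37 higher among 61 measured ion channel and gap junction genes (19 higher, 28 lower, 14 not called, with 19 and 28 adjusted over the list alone). The growth factor gene Igf1 lay at -5.74 ± 0.14 among 45 measured PDGF, EGF, IGF and endothelin genes (19 higher, 18 lower, 8 not called, with 19 and 18 adjusted over the list alone).

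Guidance genes were lower more often than higher. Nrp1, a semaphorin receptor gene, lay at -5.01 ± 0.14 among 36 measured semaphorin, netrin and slit genes (13 higher, 19 lower, 4 not called, with 13 and 19 adjusted over the list alone), and Epha3 at -4.95 ± 0.11 among 19 measured Eph and ephrin genes (6 higher, 11 lower, 2 not called, with 6 and 11 adjusted over the list alone). Genes of the dissociation and stress response were more often higher: the heat shock gene Hspb1 by 7.21 ± 0.15 (264 ± 27.0 against 1.78 ± 0.639 CPM) and Atf3, an immediate early gene, by 4.50 ± 0.13, among 39 measured dissociation and stress response genes (23 higher, 11 lower, 5 not called, with 23 and 11 adjusted over the list alone). In all, of 13998 tested genes, 4470 were higher and 4390 lower.

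Endothelium-like cells expressed vascular signalling genes that were near 0 in the mesenchyme. Edn1, an endothelial peptide hormone, was 10.68 ± 0.33 higher (75.6 ± 13.8 against 0.0400 ± 0.0353 CPM), Dll4, a Notch ligand of arterial tips, 9.94 ± 0.31 (64.8 ± 2.57 against 0.0602 ± 0.0308 CPM), and Pdgfb, which recruits mural cells, 10.38 ± 0.30. The receptors Robo4 (10.28 ± 0.26), Aplnr (10.02 ± 0.15) and Flt4 (9.31 ± 0.24) and the gap junction genes Gja4 (9.41 ± 0.26) and Gja5 (9.41 ± 0.43) were higher as well. Of 18 measured Notch pathway genes, 14 were higher, 4 lower and 0 not called (14 and 4 adjusted over the list alone). The basement membrane collagen genes Col18a1 (8.32 ± 0.11, 608 ± 50.6 against 1.88 ± 0.451 CPM) and Col15a1 (8.66 ± 0.14) were higher among 80 measured extracellular matrix genes (20 higher, 52 lower, 8 not called, with 20 and 52 adjusted over the list alone). Meox2, a homeobox gene also studied in the palate, was 2.20 ± 0.24 higher (20.0 ± 4.83 against 4.26 ± 0.542 CPM).

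Most patterning regulators were lower in the endothelium (56 measured palate patterning transcription factors (9 higher, 44 lower, 3 not called, with 9 and 44 adjusted over the list alone)). Shox2 lay at -4.02 ± 0.16, Osr2 at -3.91 ± 0.15, Barx1 at -3.98 ± 0.17 and Msx1 at -3.19 ± 0.15. Of 17 measured hedgehog genes, 0 were higher, 15 lower and 2 not called (0 and 15 adjusted over the list alone), with Ptch1 at -2.80 ± 0.15 and Gli2 at -4.04 ± 0.34. Of 32 measured BMP pathway genes, 5 were higher, 21 lower and 6 not called (5 and 21 adjusted over the list alone). Bmp4 itself was not called (-0.32 ± 0.15, edgeR adjusted p = 0.0757), but was called lower without replicate 1 (-0.51 ± 0.18) and with the stricter cell filter (-1.12 ± 0.23). Of 24 measured FGF pathway genes, 5 were higher, 13 lower and 6 not called (5 and 13 adjusted over the list alone). Of 16 measured retinoic acid pathway genes, 0 were higher, 12 lower and 4 not called (0 and 12 adjusted over the list alone), with Crabp1 at -4.51 ± 0.17 and Aldh1a2 at -4.30 ± 0.20. Of 38 measured dissociation and stress response genes, 20 were higher, 6 lower and 12 not called (21 and 6 adjusted over the list alone), with Junb at 2.73 ± 0.18. In this comparison, of 13543 tested genes, 3473 were higher and 4498 lower.

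Stress genes were mostly higher in immune-like cells: of 38 measured dissociation and stress response genes, 21 were higher, 6 lower and 11 not called (23 and 6 adjusted over the list alone). Atf3 was 7.54 ± 0.16 higher (302 ± 6.78 against 1.62 ± 0.519 CPM), Zfp36, a regulator of cytokine mRNA decay, 4.66 ± 0.11 (466 ± 56.4 against 18.5 ± 3.78 CPM), Tgfb1 5.42 ± 0.24 (126 ± 21.5 against 2.90 ± 0.395 CPM) and Nrros, which anchors latent TGF-beta on macrophages, 6.81 ± 0.29 (128 ± 13.4 against 1.13 ± 0.227 CPM). Of 28 measured TGF-beta pathway genes, 6 were higher, 14 lower and 8 not called (6 and 14 adjusted over the list alone). Few patterning genes were higher: of 54 measured palate patterning transcription factors, 1 was higher, 47 lower and 6 not called (1 and 49 adjusted over the list alone). Of 18 measured Eph and ephrin genes, 0 were higher, 17 lower and 1 not called (0 and 17 adjusted over the list alone), with Epha5 at -5.78 ± 0.44. Of 79 measured extracellular matrix genes, 5 were higher, 63 lower and 11 not called (5 and 63 adjusted over the list alone), with Col8a1 at -6.23 ± 0.40. Alx4, Dlx2 and Fzd1 had 0 UMIs in immune-like cells and were at least 13.6-fold, 11.1-fold and 16.3-fold lower.

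Shox2 lay at -3.98 ± 0.17 in immune-like cells (43.8 ± 7.40 against 681 ± 16.7 CPM) and Wnt5a, a WNT ligand gene, at -4.22 ± 0.22 among 51 measured WNT pathway genes (2 higher, 35 lower, 14 not called, with 3 and 36 adjusted over the list alone). Shox2 UMIs were present in 12.9% ± 1.11 of immune-like cells at a median of 18015 UMIs per cell. Without TMM scaling, endothelium-like cells held Shox2 at 41.4 CPM and erythroid-like cells at 39.0 CPM. These 2 values are not on the same footing, since haemoglobin genes took 78.1% of the UMIs in erythroid-like cells and so lowered the CPM of other genes. Background RNA was not separated from expression, so these low levels and detected shares need not mean that such cells express Shox2. Of 13543 tested genes, 2890 were higher and 3881 lower. The medians of all tested genes were -0.14 for endothelium-like, -0.27 for immune-like and -0.23 for Schwann-like cells against mesenchyme-like cells, so small negative values there lie near the median gene.

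Schwann-like cells, the glia of peripheral nerves, were marked by glial genes and a sodium channel gene. Rxrg, a retinoid receptor, was 11.43 ± 0.88 higher (50.6 ± 6.82 against 0.00934 ± 0.0162 CPM), the sodium channel gene Scn7a 10.44 ± 1.17 and Lgi4, a secreted protein needed for myelination, 9.50 ± 0.54 (101 ± 19.2 against 0.134 ± 0.0388 CPM). Heyl, a Notch target, was 6.47 ± 0.43 higher (105 ± 18.4 against 1.20 ± 0.976 CPM) among 14 measured Notch pathway genes (5 higher, 1 lower, 8 not called, with 5 and 1 adjusted over the list alone). Of 57 measured ion channel and gap junction genes, 16 were higher, 9 lower and 32 not called (16 and 10 adjusted over the list alone). Mesenchymal regulators were lower, with Shox2 at -5.74 ± 0.22, Msx1 at -5.97 ± 0.34, Foxf2 at -5.46 ± 0.66 and the guidance receptor Epha4 at -6.99 ± 0.48. These folds rest on few tested UMIs in Schwann-like cells: 9 of Shox2, 3 of Msx1 and 1 each of Foxf2 and Epha4. Their sizes are less certain than the SEs say. Pax9, Barx1 and Aldh1a2 had 0 UMIs and were at least 14.0-fold, 34.9-fold and 16.6-fold lower.

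Of 54 measured palate patterning transcription factors, 8 were higher, 35 lower and 11 not called (8 and 35 adjusted over the list alone). Of 78 measured extracellular matrix genes, 19 were higher, 32 lower and 27 not called (20 and 34 adjusted over the list alone). Of 36 measured semaphorin, netrin and slit genes, 7 were higher, 13 lower and 16 not called (8 and 16 adjusted over the list alone). Of 38 measured dissociation and stress response genes, 5 were higher, 10 lower and 23 not called (5 and 12 adjusted over the list alone), and the immediate early genes Egr1 (-1.76 ± 0.19) and Klf4 (-1.79 ± 0.22) were lower than in mesenchyme-like cells. Of 13123 tested genes, 1052 were higher and 1466 lower. These 81 cells formed the smallest class tested: without replicates 1 and 2 in turn 1501 and 1462 genes were called, and with DESeq2 1431. With the stricter filter 1158 were called. That filter left 7 Schwann-like cells in replicate 3, too few for a sum, so the 1158 calls rest on paired sums of replicates 1 and 2. DESeq2 put 57.0% of its calls on the higher side against 41.8% in edgeR.

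Cycling-like cells differed from the other mesenchyme-like cells by small folds in their patterning genes. Barx1, a homeobox gene, was 0.54 ± 0.03 higher in cycling-like cells (204 ± 51.5 against 140.0 ± 31.5 CPM), Pax9 0.44 ± 0.05 (79.4 ± 9.65 against 58.3 ± 6.34 CPM) and Shox2 0.22 ± 0.02 (773 ± 37.5 against 661 ± 14.0 CPM), while Osr2 (-0.22 ± 0.04) and Ptch1 (-0.28 ± 0.04) were slightly lower. Etv5 and Etv4, targets of FGF signalling, were 0.81 ± 0.05 and 0.90 ± 0.09 higher and the orphan receptor gene Nr2f1 0.91 ± 0.06. Ogn (-1.32 ± 0.06, 53.4 ± 11.4 against 134 ± 40.2 CPM), Aspn (-1.07 ± 0.05) and Igfbp5, a secreted binder of insulin-like growth factors (-1.02 ± 0.04, 105 ± 19.4 against 214 ± 56.2 CPM), were lower. Mxd4, which represses MYC targets, lay at -1.20 ± 0.04. Msx1 (0.07 ± 0.06), Bmp4 (-0.05 ± 0.05), Gli1 (-0.09 ± 0.07) and Osr1 (-0.03 ± 0.06) were not called, although Msx1 passed without replicate 2 (0.19 ± 0.03). The class includes 196 cells of a cluster led by Tfap2b, Tfap2c and Penk, and without them Barx1 lay at 0.46 ± 0.04, Pax9 at 0.37 ± 0.05 and Bmp4, then called lower, at -0.17 ± 0.05, in an alternative chosen after seeing the data.

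Of 79 measured extracellular matrix genes, 7 were higher, 42 lower and 30 not called (7 and 42 adjusted over the list alone). Of 55 measured palate patterning transcription factors, 14 were higher, 13 lower and 28 not called (14 and 13 adjusted over the list alone). Of 38 measured dissociation and stress response genes, 10 were higher, 18 lower and 10 not called (10 and 18 adjusted over the list alone), with Hsp90aa1 at 0.82 ± 0.02 and Ier3 at -0.996 ± 0.07. Of 36 measured semaphorin, netrin and slit genes, 3 were higher, 15 lower and 18 not called (3 and 15 adjusted over the list alone), with Robo2 at -0.59 ± 0.05. Cell cycle genes took no part in this comparison. Of 13395 tested genes, 3564 were higher and 3204 lower; the share on the higher side was 52.7% in edgeR with TMM, 39.7% with library-size scaling alone and 63.1% with DESeq2, which called 3664 genes, so no balance between directions is read from it. Without the library block 3802 genes were called, and the calls of Barx1 and Osr2 were lost.

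Within the mesenchyme, 11 clusters were drawn without any of the 603 genes of the fixed lists, so the list genes described for each cluster took no part in forming it. Shares of the mesenchyme ran from 14.0% ± 1.02 for cluster 1 to 3.37% ± 1.16 for cluster 11, and they depend on the processing: 49 of 120 alternatives moved a cluster's share by at least 1 SD between libraries. Cluster 1 matched at a Jaccard index of only 0.323 both at a mesenchymal resolution of 1.0 and with cell cycle scores left in. Clusters 2 and 9 differed most between libraries, with 19.1%, 13.2% and 9.18% for cluster 2 and 2.35%, 3.62% and 10.2% for cluster 9 in replicates 1, 2 and 3. Each cluster was tested against the sum of all others in the same libraries. DESeq2 called between 0.434 and 0.78 times as many genes as edgeR over the 18 comparisons, and leaving out the library block lowered the counts of 8 of the 11 clusters by more than 1.5 times. Leading genes given at the start of each account describe the cluster in the counts used for clustering; they are not results of the test.

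**Figure D2:**
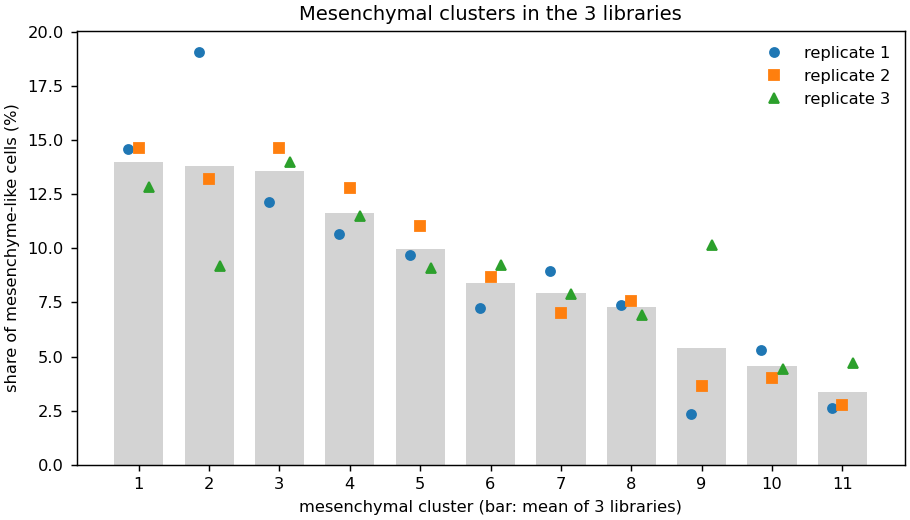
Share of each of the 11 mesenchymal clusters among mesenchyme-like cells, in percent, with 1 point per library and the mean as a bar. Cluster 9 spans 2.35% to 10.2% and cluster 2 spans 9.18% to 19.1%, while cluster 8 stays between 6.94% and 7.58%.

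Cluster 1 led with genes of mitosis (Cenpf, Cdc20, Ccnb2). Tbx22, the gene of X-linked cleft palate, was 2.87 ± 0.21 higher there (9.63 ± 7.54 against 1.28 ± 0.741 CPM), Nr2f1 2.06 ± 0.06 (178 ± 26.1 against 42.7 ± 6.59 CPM), Crabp2, a retinoic acid binding protein gene, 0.93 ± 0.04 (283 ± 25.9 against 149 ± 13.8 CPM) and Shox2 0.58 ± 0.03 (957 ± 61.9 against 639.6 ± 18.4 CPM). Tfap2b was lower at -5.26 ± 0.13, Smoc2 at -2.71 ± 0.15 and Igfbp5 at -2.32 ± 0.10 (41.2 ± 21.0 against 205 ± 46.7 CPM). The calls of Tbx22 and Tfap2b were lost with cell cycle scores left in, and that of Tbx22 also at a mesenchymal resolution of 1.0, where 2850 genes were called. Osr2 (-0.09 ± 0.05) and Osr1 (-0.03 ± 0.09) were not called. Without replicate 1, Osr2 was called lower (-0.17 ± 0.05), and at a mesenchymal resolution of 1.0 both were called higher (0.16 ± 0.05 and 0.48 ± 0.11). Of 53 measured palate patterning transcription factors, 16 were higher, 24 lower and 13 not called (18 and 24 adjusted over the list alone). Of 38 measured dissociation and stress response genes, 4 were higher, 21 lower and 13 not called (4 and 22 adjusted over the list alone). In total, of 13387 tested genes, 2396 were higher and 2137 lower.

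Cluster 2 led with Rmst, Mecom and Col9a1. The retinoic acid genes Aldh1a2, the synthesising enzyme, and Rarb, a receptor and target, were 2.34 ± 0.05 (239.9 ± 81.8 against 47.3 ± 13.1 CPM) and 2.91 ± 0.08 higher (79.4 ± 4.79 against 10.5 ± 1.09 CPM). Ebf3 (3.51 ± 0.11), Foxp2 (2.79 ± 0.07), Ogn (2.91 ± 0.04, 439.7 ± 38.0 against 58.4 ± 5.48 CPM), Gdf10 (2.94 ± 0.08), Barx1 (1.46 ± 0.08, 356 ± 96.1 against 129 ± 25.7 CPM) and Kcnj2, the potassium channel gene of Andersen-Tawil syndrome, (2.20 ± 0.08, 69.7 ± 8.30 against 15.2 ± 1.90 CPM) were higher too. Osr2 was nearly absent at -4.55 ± 0.11 (8.92 ± 2.67 against 219 ± 17.8 CPM), and Pax9 (-2.62 ± 0.09), Ptch1 (-2.83 ± 0.09, 52.9 ± 14.4 against 378 ± 16.4 CPM) and Shox2 (-2.38 ± 0.05, 151 ± 17.6 against 779 ± 40.3 CPM) were lower, while Msx1 was not called (-0.13 ± 0.05) except without replicate 3 (-0.17 ± 0.06) and, in both directions, under other clusterings. Of 54 measured palate patterning transcription factors, 24 were higher, 20 lower and 10 not called (24 and 21 adjusted over the list alone). Of 17 measured hedgehog genes, 3 were higher, 8 lower and 6 not called (4 and 10 adjusted over the list alone). Of 40 measured PDGF, EGF, IGF and endothelin genes, 17 were higher, 9 lower and 14 not called (19 and 9 adjusted over the list alone). Over all genes, of 13504 tested genes, 1606 were higher and 2108 lower; a mesenchymal resolution of 1.0 gave 2436 calls.

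Cluster 3 led with Cplx2, Cped1 and Fam129a. Ptch1 was 1.495 ± 0.04 higher (775 ± 50.1 against 276 ± 19.1 CPM), Hhip 1.88 ± 0.12 and Foxl1 2.58 ± 0.16. Osr2 was 1.47 ± 0.03 higher (438 ± 38.0 against 158 ± 19.5 CPM), Shox2 1.43 ± 0.03 (1562 ± 49.6 against 578 ± 21.1 CPM), the WNT inhibitor gene Wif1 1.99 ± 0.09 and the Notch ligand gene Dll1 3.70 ± 0.28. Dlx5 (-5.88 ± 0.26), Rarb (-4.09 ± 0.20), Gdf10 (-4.21 ± 0.19), Bmp4 (-2.24 ± 0.10, 12.5 ± 3.99 against 58.1 ± 7.24 CPM), Barx1 (-1.73 ± 0.05) and Msx1 (-1.42 ± 0.06) were lower, and Panx3 had 0 UMIs, at least 11-fold lower. Of 17 measured hedgehog genes, 9 were higher, 4 lower and 4 not called (9 and 4 adjusted over the list alone). Of 32 measured BMP pathway genes, 11 were higher, 19 lower and 2 not called (11 and 20 adjusted over the list alone). Tbx22 (0.19 ± 0.30) and Meox2 (0.41 ± 0.21) were not called here, while other clusterings called Tbx22 in either direction. Of 13360 tested genes, 2339 were higher and 2544 lower.

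Cluster 4 led with Ndnf, Asb4 and Cited2. Osr1 was 1.45 ± 0.09 higher (67.1 ± 9.28 against 24.8 ± 5.15 CPM), Meox2 1.68 ± 0.17 (11.3 ± 1.22 against 3.54 ± 0.448 CPM), Fgf10, a ligand for the epithelial FGF receptor, 1.31 ± 0.08 (60.3 ± 1.53 against 24.3 ± 1.88 CPM), Dlk1 1.29 ± 0.08 and the BMP antagonist gene Chrdl1 3.00 ± 0.14 (35.1 ± 7.25 against 4.43 ± 0.944 CPM). Lef1 (-2.82 ± 0.18), Col12a1 (-3.15 ± 0.12) and Tbx15 (-3.20 ± 0.23) were lower. Ptch1 (0.02 ± 0.04), Barx1 (-0.05 ± 0.05) and Gli1 (0.19 ± 0.10) were not called, and Barx1 was called lower without replicate 3 (-0.14 ± 0.05). Of 32 measured BMP pathway genes, 1 was higher, 18 lower and 13 not called (1 and 19 adjusted over the list alone). Of 24 measured FGF pathway genes, 2 were higher, 15 lower and 7 not called (2 and 17 adjusted over the list alone). Of 79 measured extracellular matrix genes, 9 were higher, 41 lower and 29 not called (10 and 44 adjusted over the list alone). In cluster 4, of 13305 tested genes, 1323 were higher and 1755 lower; the stricter cell filter left 1924.

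Cluster 5 led with Pcp4, Cd200 and En1. Bmp4 was 1.46 ± 0.08 higher (121 ± 14.9 against 44.4 ± 8.11 CPM), Msx1 0.69 ± 0.04 (412 ± 33.8 against 256 ± 24.2 CPM), Tbx15 2.19 ± 0.17 (57.9 ± 3.82 against 13.7 ± 7.94 CPM), Epha5 1.67 ± 0.08 (215 ± 32.4 against 68.7 ± 13.8 CPM) and the sodium channel gene Scn3a 1.88 ± 0.09. Osr2 (-2.93 ± 0.06, 27.1 ± 1.55 against 207 ± 26.6 CPM), Osr1 (-3.05 ± 0.19), Shox2 (-2.03 ± 0.04, 181 ± 18.9 against 743 ± 24.1 CPM), Pax9 (-2.33 ± 0.10), Nr2f1 (-3.83 ± 0.16) and the semaphorin receptor gene Nrp1 (-3.46 ± 0.07) were lower, and Foxl1 had 0 UMIs, at least 17.0-fold lower. Stress genes were mostly higher: of 38 measured dissociation and stress response genes, 22 were higher, 3 lower and 13 not called (25 and 3 adjusted over the list alone), with Fosl2 at 1.77 ± 0.13. Of 79 measured extracellular matrix genes, 34 were higher, 23 lower and 22 not called (35 and 26 adjusted over the list alone). Of 24 measured FGF pathway genes, 5 were higher, 14 lower and 5 not called (5 and 14 adjusted over the list alone). Of 13386 tested genes, 1969 were higher and 2049 lower.

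Cluster 6 led with Rorb, Fendrr and Prickle1. Foxf1, a hedgehog target, was 1.96 ± 0.06 higher (247 ± 7.53 against 63.4 ± 2.33 CPM), Ptch1 1.24 ± 0.05 (713 ± 50.6 against 303 ± 10.9 CPM), Osr2 1.30 ± 0.05 (425 ± 67.1 against 172 ± 20.6 CPM), Sostdc1, an inhibitor of BMP and WNT signalling, 3.07 ± 0.08 (433 ± 25.1 against 51.8 ± 5.54 CPM), Dkk2 2.58 ± 0.13 and Aldh1a1 4.18 ± 0.30. Kcnj2 (-5.35 ± 0.34, 0.579 ± 0.503 against 23.8 ± 5.37 CPM), Gdf10 (-4.48 ± 0.28), Dlx5 (-4.31 ± 0.29) and Gsc (-4.22 ± 0.41) were lower. Wnt5a (-0.02 ± 0.05) and Pax9 (-0.14 ± 0.08) were not called, and both were called in either direction under other clusterings. Of 17 measured hedgehog genes, 10 were higher, 2 lower and 5 not called (10 and 2 adjusted over the list alone). Of 38 measured dissociation and stress response genes, 17 were higher, 10 lower and 11 not called (17 and 10 adjusted over the list alone), with Junb at 1.63 ± 0.13. Of 39 measured PDGF, EGF, IGF and endothelin genes, 16 were higher, 6 lower and 17 not called (20 and 8 adjusted over the list alone). Of 13368 tested genes, 1630 were higher and 1922 lower; without replicate 3 the count was 2143, and with cell cycle scores left in 5458.

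Cluster 7 led with Prg4, Nppc and Adamts5. Epha3 was 2.89 ± 0.04 higher (795 ± 88.2 against 108 ± 20.6 CPM), Pax3 2.36 ± 0.10 (89.5 ± 20.5 against 17.5 ± 6.77 CPM), Foxd2 2.38 ± 0.11, Pax9 1.62 ± 0.07 (175 ± 1.23 against 56.7 ± 7.65 CPM), Wnt5a 1.26 ± 0.04 (458 ± 23.3 against 192 ± 5.42 CPM), Shox2 1.12 ± 0.03 and Osr2 1.20 ± 0.04, a call lost with features left uncentred within libraries. Barx1 was lower at -4.78 ± 0.12 (6.36 ± 1.46 against 169 ± 42.4 CPM), Dlx5 at -6.53 ± 0.36, Dlx1 at -6.68 ± 0.36, Meox2 at -3.31 ± 0.55 and Foxf1 at -2.23 ± 0.10. Of 18 measured Eph and ephrin genes, 10 were higher, 4 lower and 4 not called (10 and 4 adjusted over the list alone). Of 24 measured FGF pathway genes, 13 were higher, 5 lower and 6 not called (13 and 5 adjusted over the list alone), with Fgf18 at 1.97 ± 0.14. Of 55 measured palate patterning transcription factors, 12 were higher, 31 lower and 12 not called (14 and 31 adjusted over the list alone). Of 13307 tested genes, 1839 were higher and 2212 lower; the uncentred features gave 2039 calls and a mesenchymal resolution of 1.0 gave 2451.

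Cluster 8 led with replication-dependent histone genes. Shox2 was 0.32 ± 0.03 higher, Hsp90aa1 0.67 ± 0.03 (1300.0 ± 65.0 against 817 ± 58.0 CPM) and Aldh1a3 1.36 ± 0.13, and the matrix genes Ogn (-1.47 ± 0.08, 40.1 ± 8.60 against 112 ± 28.4 CPM) and Aspn (-0.96 ± 0.07) were lower. Wnt5a (-0.02 ± 0.05), Osr1 (0.08 ± 0.11) and Gli1 (-0.12 ± 0.10) were not called. Wnt5a was called higher at the mesenchymal resolution of 1.0 (0.24 ± 0.05) and with cell cycle scores left in (0.11 ± 0.04), and lower with library-size scaling (-0.15 ± 0.05). Of 79 measured extracellular matrix genes, 5 were higher, 28 lower and 46 not called (5 and 28 adjusted over the list alone). Of 55 measured palate patterning transcription factors, 17 were higher, 13 lower and 25 not called (17 and 15 adjusted over the list alone). Of 13318 tested genes, 2685 were higher and 2156 lower; 55.5% of the calls were on the higher side, 29.8% with library-size scaling, which moved the median of all genes from -0.02 to -0.16, and 66.6% with DESeq2, and without replicate 2 the count was 3058.

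Cluster 9 led with Smpd3 and Gria2, and Sp7 was further down among its leading genes. The bone markers Alpl, Sp7 and Runx2 and the cartilage markers Matn4, Sox6 and Sox9 were at least 2-fold above the rest. Alpl and Runx2 also reached 2-fold in cluster 5, and Sox6 in clusters 2, 5 and 11. Panx3, a channel gene of skeletal cells, was 6.23 ± 0.39 higher (42.6 ± 15.5 against 0.562 ± 0.401 CPM), Dlx3 4.35 ± 0.33 (22.5 ± 4.70 against 1.07 ± 0.413 CPM), Bmp2 2.93 ± 0.11 (118 ± 19.4 against 15.2 ± 0.636 CPM), Smoc2 3.46 ± 0.11 (272 ± 70.7 against 25.7 ± 12.4 CPM), Col12a1 3.38 ± 0.13 (473 ± 103 against 44.5 ± 6.04 CPM), Fgfr3 3.34 ± 0.24 and Msx1 0.78 ± 0.06. Shox2 (-3.37 ± 0.12, 70.4 ± 23.2 against 721 ± 29.8 CPM), Osr2 (-3.54 ± 0.21, 13.6 ± 13.4 against 199.5 ± 32.4 CPM), Igf1 (-4.59 ± 0.19) and Alx1 (-3.75 ± 0.19) were lower, and Meox2 had 0 UMIs, at least 8.65-fold lower. Barx1 (0.01 ± 0.14) and Bmp4 (-0.06 ± 0.18) were not called, but both were called lower without replicate 3 (-0.38 ± 0.10 and -0.67 ± 0.18), which holds most cells of this cluster. Of 33 measured BMP pathway genes, 14 were higher, 6 lower and 13 not called (15 and 7 adjusted over the list alone). Of 81 measured extracellular matrix genes, 31 were higher, 26 lower and 24 not called (32 and 31 adjusted over the list alone). Of 18 measured hedgehog genes, 2 were higher, 7 lower and 9 not called (2 and 8 adjusted over the list alone). Of 13366 tested genes, 1376 were higher and 1368 lower.

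Cluster 10 led with Tfap2c, Enpp1 and Penk. Tfap2b, a neural crest transcription factor gene, was 6.70 ± 0.13 higher (627 ± 126 against 6.24 ± 3.01 CPM), Lef1, a WNT effector gene of tooth mesenchyme, 3.22 ± 0.26 (169 ± 78.6 against 20.1 ± 14.8 CPM), Msx1 1.75 ± 0.07 (820.4 ± 79.4 against 244 ± 27.3 CPM), Barx1 1.47 ± 0.07 (398 ± 74.7 against 145 ± 35.7 CPM), Bmp4 1.18 ± 0.10, Pax9 1.11 ± 0.10 and Fgf3 7.73 ± 0.66 (8.34 ± 3.15 against 0.0344 ± 0.0363 CPM). The FGF feedback inhibitor genes Spry4 and Spry1 were 2.74 ± 0.11 and 2.58 ± 0.14 higher. Shox2 was lower at -2.80 ± 0.10 (105 ± 27.7 against 729 ± 12.3 CPM), Osr1 at -4.17 ± 0.26, Meis2 at -3.53 ± 0.11 and Alx1 at -3.78 ± 0.15. Of 25 measured FGF pathway genes, 9 were higher, 5 lower and 11 not called (9 and 5 adjusted over the list alone). Of 32 measured BMP pathway genes, 11 were higher, 8 lower and 13 not called (12 and 8 adjusted over the list alone). Of 16 measured retinoic acid pathway genes, 3 were higher, 7 lower and 6 not called (3 and 10 adjusted over the list alone), with Crabp1 at -2.37 ± 0.08. Of 13335 tested genes, 1388 were higher and 1344 lower; the count without replicate 3 was 1279, with the stricter filter 1579 and at a mesenchymal resolution of 1.0 it was 1768.

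Cluster 11, the smallest, led with Cxcl14, Adamtsl1 and Egfl6. Bmper, which binds BMPs, was 2.85 ± 0.24 higher (36.2 ± 12.7 against 5.02 ± 0.968 CPM), Sema3d 2.45 ± 0.12 (108 ± 16.3 against 19.6 ± 5.42 CPM), Ephb1 2.16 ± 0.15 (72.5 ± 24.5 against 15.8 ± 1.43 CPM), Epha3 0.95 ± 0.09 and Msx1 0.78 ± 0.07. Barx1 was lower at -3.90 ± 0.17 (11.2 ± 8.29 against 162 ± 37.4 CPM), Nr2f1 at -3.99 ± 0.26 and Foxf1 at -3.27 ± 0.20. Shox2 (-1.11 ± 0.07) and Osr2 (-3.03 ± 0.16) were lower too. With the stricter cell filter neither was called, and the direction of Shox2 turned (0.18 ± 0.08), while Osr2 lay at -0.10 ± 0.11. The call of Shox2 was also lost without doublet removal (-0.15 ± 0.06). Of 18 measured Eph and ephrin genes, 6 were higher, 3 lower and 9 not called (7 and 3 adjusted over the list alone). Of 55 measured palate patterning transcription factors, 9 were higher, 28 lower and 18 not called (9 and 30 adjusted over the list alone). Of 79 measured extracellular matrix genes, 22 were higher, 18 lower and 39 not called (25 and 20 adjusted over the list alone). Of 13331 tested genes, 773 were higher and 1091 lower; without replicate 3 there were 1112, with the stricter filter 1209.

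**Figure D3:**
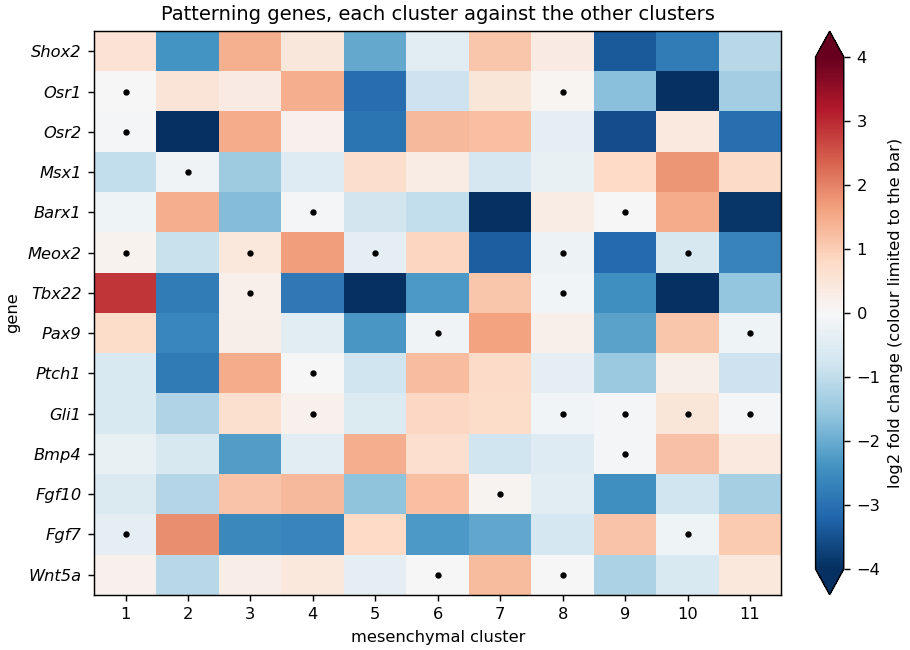
Log2 fold change of 14 patterning genes in each mesenchymal cluster against the other clusters, in colour from blue (lower) to red (higher), limited to the range of the colour bar, with a dot where the gene was not called and genes without UMIs at their bound. Osr2 and Shox2 are red together in clusters 3 and 7 and blue together in clusters 2, 5, 9 and 11. They were called in opposite directions in clusters 6 and 10 (Osr2 higher, Shox2 lower) and in cluster 8 (Shox2 higher, Osr2 lower). Barx1 and Msx1 are red together in cluster 10.

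Mesenchyme-like cells were then divided by whether Shox2 had a UMI in the part of the counts kept for clustering, and the separate part was tested. Shox2 was detected in 71.1% ± 3.98 of the cells and was 9.4 ± 1.46 times higher in the tested counts of these. Detected cells had more Osr2 (1.42 ± 0.05, 232 ± 31.2 against 86.6 ± 12.8 CPM), Nr2f1 (2.77 ± 0.14, 84.5 ± 11.9 against 12.2 ± 6.91 CPM), Nrp1 (1.93 ± 0.11, 202 ± 5.81 against 52.8 ± 12.9 CPM), Fgf10 (1.34 ± 0.07), Ptch1 (0.93 ± 0.04), Wnt5a (0.93 ± 0.04) and Tbx18 (3.81 ± 0.39). They had less Barx1 (-1.39 ± 0.07, 109.5 ± 21.0 against 292 ± 92.0 CPM), Igfbp5 (-2.19 ± 0.06, 90.8 ± 20.2 against 412 ± 68.0 CPM), Msx1 (-0.90 ± 0.05), Tfap2b (-2.53 ± 0.13), Lef1 (-1.99 ± 0.08) and Aldh1a2 (-1.79 ± 0.16). Tbx22 (0.50 ± 0.50) and Osr1 (0.25 ± 0.17) were not called, but both were called higher without replicate 1 (3.47 ± 0.64 and 0.69 ± 0.10).

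Of 17 measured hedgehog genes, 8 were higher, 2 lower and 7 not called (8 and 2 adjusted over the list alone). Of 33 measured BMP pathway genes, 6 were higher, 18 lower and 9 not called (7 and 19 adjusted over the list alone). Of 55 measured palate patterning transcription factors, 19 were higher, 26 lower and 10 not called (19 and 27 adjusted over the list alone). Of 18 measured Eph and ephrin genes, 5 were higher, 2 lower and 11 not called (6 and 2 adjusted over the list alone), with Efnb1 at 0.94 ± 0.04. In all, of 13337 tested genes, 1641 were higher and 1905 lower. With sums kept within each mesenchymal cluster, 407 genes were called, against 3546 without that step. After thinning, Shox2 was detected in 22.0% of cluster 9 and in 99.2% of cluster 3. The division thus also sorts cells by cluster, and its folds include differences between clusters. Without the library block 1539 genes were called, and with DESeq2 1614.

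The same division by Osr2 (ENSMUSG00000022330, chromosome 15, 35296098 to 35303305, plus strand), a zinc finger gene of palatal outgrowth, found it in 44.6% ± 3.07 of the cells, with 5.17 ± 0.352 times more Osr2 in the tested counts of these. With Osr2, Ptch1 was 1.40 ± 0.04 higher (508 ± 9.64 against 193 ± 21.5 CPM), Hhip 1.62 ± 0.09 and Gli1 0.65 ± 0.08. Shox2 (1020.0 ± 4.29 against 429 ± 19.2 CPM), Fgf10 (1.39 ± 0.06), Pax9 (1.13 ± 0.04), Foxl1 (2.84 ± 0.18), Wif1 (1.95 ± 0.11) and Nrp1 (1.83 ± 0.05) were higher as well. Dlx5 (-3.68 ± 0.10, 3.58 ± 1.09 against 46.4 ± 8.26 CPM), Dlx3 (-3.01 ± 0.32), Panx3 (-3.86 ± 0.30), Gdf10 (-3.44 ± 0.13), Rarb (-2.51 ± 0.09) and Ogn (-2.31 ± 0.04, 34.2 ± 7.89 against 169 ± 40.7 CPM) were lower. Msx1 (-0.52 ± 0.04) and Barx1 (-0.81 ± 0.05) were lower by less.

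Of 17 measured hedgehog genes, 9 were higher, 2 lower and 6 not called (9 and 3 adjusted over the list alone). Of 27 measured FGF pathway genes, 14 were higher, 7 lower and 6 not called (15 and 7 adjusted over the list alone). Of 16 measured retinoic acid pathway genes, 9 were higher, 5 lower and 2 not called (9 and 5 adjusted over the list alone). Of 51 measured WNT pathway genes, 19 were higher, 15 lower and 17 not called (19 and 17 adjusted over the list alone). Among 38 measured dissociation and stress response genes, 4 were higher, 17 lower and 17 not called (4 and 17 adjusted over the list alone). Of 13421 tested genes, 2123 were higher and 2435 lower. Sums within each mesenchymal cluster called 931, fits without the library block 1747 and DESeq2 1979. After thinning, Osr2 was detected in 3.59% of cluster 2 and in 77.1% of cluster 3, so these folds include differences between clusters as well.

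Pairs of patterning genes were compared cell by cell after thinning each mesenchyme-like cell to 4000 UMIs, which left 18653 cells and dropped 327. Of 300 pairs of 25 genes, 273 could be scored. Among these, 96 had a log2 odds ratio above 0 in all 3 libraries, 110 below 0 in all 3 and 67 were mixed. Random signs would give 12.5% for each of the first 2 groups. The same clusters recur in each library, so shared signs could be foreseen for genes that differ between clusters. Shox2 and Osr2, for example, were detected in 99.2% and 77.1% of cluster 3 and in 34.4% and 3.59% of cluster 2 after thinning. The odds ratios run over all mesenchyme-like cells, so they do not separate differences between clusters from association within a cluster. Shox2 with Osr2 had the highest mean of the pairs with a shared sign (2.20 ± 0.146, SD), with Osr2 and Ptch1 at 2.16 ± 0.176, Foxf2 and Ptch1 at 1.64 ± 0.246 and Shox2 and Fgf10 at 1.48 ± 0.380. Means were also positive for Runx2, a master regulator of bone, with Dlx5 (2.07 ± 0.235) and Msx1 (1.52 ± 0.225). Of the pairs below 0 in all 3 libraries, 5 are given: Osr2 with Dlx5 at -4.11 ± 0.766, Osr2 with Runx2 at -2.63 ± 0.185, Shox2 with Runx2 at -2.20 ± 0.352, Pax9 with Dlx5 at -2.13 ± 0.172 and Osr2 with Fgf7 at -2.34 ± 0.378. Shox2 and Tbx22 gave -0.46, 2.94 and 4.98 in replicates 1, 2 and 3 and so shared no sign. With no thinning Dlx5 and Runx2 rose to 3.30, and over the 11 named pairs 13 of 66 alternatives moved the mean by at least 1 SD between libraries, with no change of sign. The named pairs were chosen after their values were seen. These are values per library with no test, since cells of a library are not replicates.

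**Figure D4:**
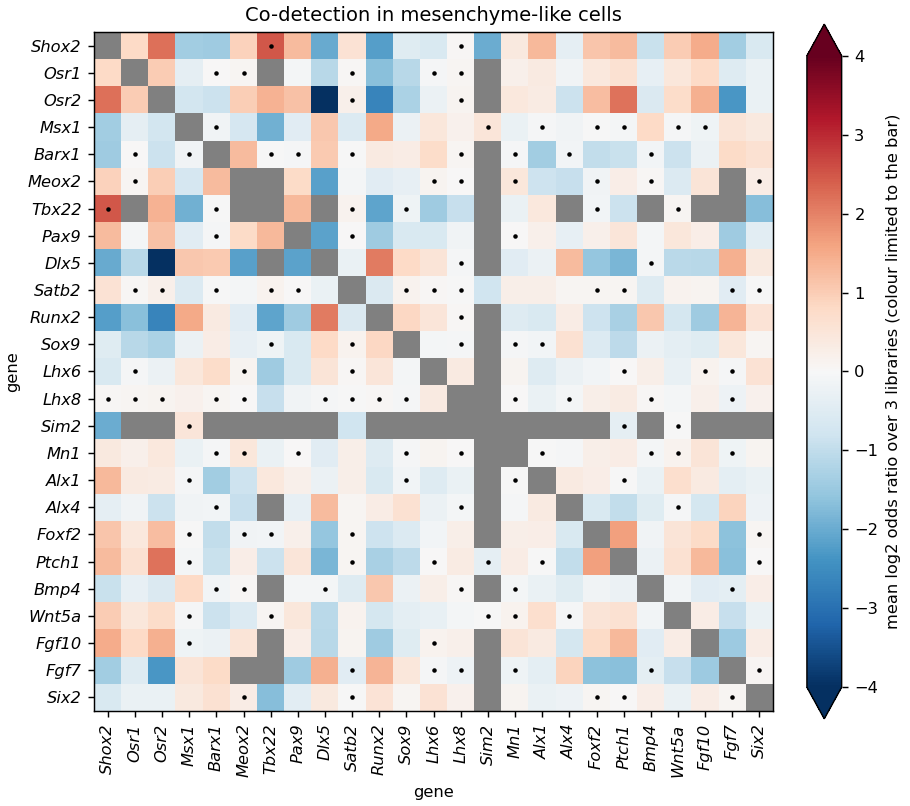
Mean log2 odds ratio of co-detection over 3 libraries for pairs of 25 patterning genes in mesenchyme-like cells thinned to 4000 UMIs, from blue (detected together less often than independence gives) to red (more often); grey marks pairs with too few expected cells and a dot marks pairs whose libraries differ in sign. Osr2 is red with Shox2 and Ptch1 and blue with Dlx5 and Runx2.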

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

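The 2 tests weighed here, on shallow cells, were written down before their results were seen, and the choice of cells and genes was made after the clusters had been seen.

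RNA of named genes was counted in cells that entered no comparison, as CPM of all their UMIs without TMM scaling. The limits given are those of a count of 0, not of background RNA. Cells of cluster 12 received no class name but carried Shox2 at 560.0 CPM (1025 UMIs in 955 cells, against a limit of 1.64 CPM), with 449, 649 and 681 CPM in replicates 1, 2 and 3. Cells of cluster 24, also without a name, carried Pecam1, an endothelial adhesion gene, at 394 CPM (78 UMIs in 109 cells, limit 15.2 CPM). The values were 587, 355 and 424 CPM in replicates 1, 2 and 3, from 17, 82 and 10 cells, so those of replicates 1 and 3 rest on few cells. Cluster 24 held Cdh5 at 788 CPM and Flt1 at 420.0 CPM, and also Shox2 at 349 CPM. Endothelium-like cells held Pecam1 at 588 CPM and Shox2 at 41.4 CPM. Erythroid-like cells held Shox2 at 39.0 CPM, a value lowered by the haemoglobin genes, which took 78.1% of their UMIs. Erythroid-like cells carried Hbb-y, an embryonic globin gene, at 359000 CPM (801692 of 2230146 UMIs in 134 cells, limit 1.35 CPM), a level that follows from the haemoglobin share used to name them.

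The cells of cluster 12 (446, 355 and 154 in replicates 1, 2 and 3) had median UMI counts of 1686, 1448 and 1710.5, far under the 9663 of mesenchyme-like cells. If they were empty droplets with free RNA, epithelium-like markers should take the same share of UMIs as in their whole library. The ratio was 0.719 in the median library, with 0.719, 0.953 and 0.428 in replicates 1, 2 and 3, which lies on both sides of what was written in advance, so empty droplets and shallow mesenchymal cells cannot be told apart. Cells that lost cytoplasm but kept mitochondria should hold more mitochondrial RNA than mesenchyme-like cells. The ratio was 0.854 (0.519, 0.854 and 0.945), which argues against that kind of loss in the cells kept. A loss that took the mitochondria too would not raise the ratio, so the test cannot decide on it. Genes with the highest ratio to all other cells included AY036118, Gm42418, Lars2 and histone genes. All cells of cluster 12 had passed the limit of 10.0% mitochondrial UMIs, so damaged cells above it had been removed before the ratio was taken. Krt14, an epithelial keratin gene, stood at 89.1 CPM in cluster 12 and 2.89 CPM in mesenchyme-like cells, so some RNA of other cells may be present, and no biological explanation was tested.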

How the results depend on the processing

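The removal of the highest-scoring doublet share in every library and the cycling comparison without the cluster led by Tfap2b were alternatives chosen after the data were seen, and the other tests given here were fixed beforehand. Everything rests on 3 libraries of 1 stage and 1 tissue, whose labels leave their origin open. Clusters and their tests share the same cells, and the p-values rest on a spread estimated partly from all genes together. They do not measure how evenly a gene differed across these libraries. Osr2 in Schwann-like cells, at 21.8 ± 25.6 CPM, still had an edgeR adjusted p of 1.27e-33. Genes printed in the report were preferred where their calls held, so their stability (3601 of 3611 alternatives the same) is chosen and not measured. Over all 1392 called genes that the rule selects, 19632 of 20855 alternatives gave the same call, 1105 ended it and 118 turned its direction, and 415 genes (29.8%) changed under at least 1. Among the 1151 not printed, 408 (35.4%) did. DESeq2 ended 156 of 1376 calls, fitting without the replicate block 147 of 1392, and sums per library and cluster 15 of 87. Clusters without a match under an alternative (4 at a mesenchymal resolution of 0.25) are in none of these counts. Of 272 alternatives for the number of called genes, 228 stayed within 1.5 times.

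Mesenchymal cluster shares moved by at least 1 SD between libraries in 49 of 120 alternatives, and means of named pairs in 13 of 66. Class shares moved that far in 8 of 88, most with stricter filtering, which gave mesenchyme-like cells 90.22%, epithelium-like 7.918%, endothelium-like 0.77%, erythroid-like 0%, cells without a name 0.1228% and cycling-like 31.73%. Cycling-like cells took 19.84% with all UMIs and 26.53% without doublet removal.

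With DESeq2 the genes called numbered 1431 for Schwann-like cells, 3664 for cycling-like cells, 1614 for Shox2 and 1979 for Osr2. For mesenchymal clusters 1 to 11 they numbered 2358, 2038, 2617, 1448, 2178, 2231, 2288, 2649, 1686, 1568 and 960.0. Without the replicate block edgeR called 1539 genes for Shox2, 1747 for Osr2 and 3802 for cycling-like cells. It called 2163, 2306, 2961, 1391, 2127, 2605, 3037 and 1084 for clusters 1, 2, 3, 4, 5, 7, 8 and 11 without that block.

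Stricter filtering gave 1158 for Schwann-like cells and 1924, 1579 and 1209 for clusters 4, 10 and 11. The 1158 rest on paired sums of replicates 1 and 2, since replicate 3 then held fewer than 10.0 Schwann-like cells. A mesenchymal resolution of 1.0 gave 2850, 2436, 2451 and 1768 for clusters 1, 2, 7 and 10. Cluster 6 had 5458 with cell cycle scores left in, and cluster 7 had 2039 without centring. Sums per library and cluster gave 407 for Shox2 and 931 for Osr2. Without 1 replicate at a time the counts ran from 1462 to 1999 for Schwann-like cells, and from 2143 to 3712, 3058 to 4348, 1279 to 2782 and 1112 to 1552 for clusters 6, 8, 10 and 11.

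Among named genes, directions turned as follows, where only Shox2 in cluster 11 had been called, and the cause was not tested. Stricter filtering gave log2 changes of 0.18 for Shox2 in cluster 11, 0.24 for Osr2 in cluster 1 and 0.25 for Wnt5a in cluster 6. A resolution of 1.0 gave 0.48 for Osr1 and 0.16 for Osr2 in cluster 1, 0.24 for Wnt5a in cluster 8 and -0.41 for Barx1 in cluster 9. A resolution of 0.25 gave 0.49 for Msx1 in cluster 2 and 0.51 for Pax9 in cluster 6. All UMIs gave 0.14 for Osr2 in cluster 1, -1.03 for Tbx22 in cluster 3 and 0.66 for Pax9 in cluster 6. The same doublet share in every library gave -1.36 for Tbx22 in cluster 3 and 0.62 for Pax9 in cluster 6. List genes among the features gave -2.26 for Tbx22 in cluster 3. Cell cycle scores left in gave 0.14 and 0.11 for Wnt5a in clusters 6 and 8, and no centring gave 0.14 for Wnt5a in cluster 6. Leaving out libraries moved Barx1 between 0.25 (without replicate 1) and -0.35 (without replicate 2) in epithelium-like cells, and between 0.22 (without replicate 1) and -0.38 (without replicate 3) in cluster 9.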

Other observations

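The genes and clusters of the next 2 paragraphs and both patterns weighed after them were chosen after their values were seen, as were the tests on UMI depth and on splits of the sums, while the other tests were written down beforehand.

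The epithelium parted into 5 clusters, described here by levels with no test (mean ± SD over 3 libraries, log2 ratios against the other epithelial clusters with 5.0 CPM added). Cluster 13, 34.0% ± 6.24 of the epithelium, carried most of the Shh (239 ± 15.7 against 27.0 ± 13.0 CPM, log2 ratio 3.00 ± 0.497), with Sim2 at 2.06 ± 0.403, Barx1 at 1.33 ± 0.259 and Ptch1 at 1.14 ± 0.162, each higher in 3 of 3 libraries. Cluster 17, 17.8% ± 1.83, was low in Shh (4.51 ± 3.94 against 94.2 ± 12.5 CPM) and was highest in Fgf9 (438 ± 27.2 against 116 ± 11.6 CPM, log2 ratio 1.87 ± 0.179) and Fst (498 ± 60.4 against 200.5 ± 4.98 CPM). Shh and Fgf9 were not among the genes that formed the clusters, and they were highest in different clusters.

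Cluster 18, 12.3% ± 4.75 of the epithelium, combined keratin genes with those of the periderm, the flat outer layer: Krt6a (92.3 ± 24.4 against 0.799 ± 1.15 CPM), Grhl3 (125 ± 22.1 against 5.97 ± 1.88 CPM) and Cldn23 (85.1 ± 27.3 against 1.47 ± 0.559 CPM). Cluster 20, 10.2% ± 7.34, held Frem1 (108 ± 28.8 against 3.13 ± 0.155 CPM) and Lef1 (125 ± 42.0 against 28.5 ± 5.10 CPM). Cluster 16, 25.7% ± 2.44, had 9 cycling markers at 2-fold.

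Mesenchymal cluster 9, with its bone and cartilage markers, took 2.35%, 3.62% and 10.2% of the mesenchyme in replicates 1, 2 and 3. Centring within libraries could have made this gap, yet without centring the highest share was 5.28 times the lowest (2.09%, 3.40% and 11.1%), and with the same doublet rule in every library it was 4.54 times (2.20%, 3.40% and 9.98%). Depth is argued against by median UMI counts of 9180 in replicate 3 and 9479 in replicate 1, a ratio of 0.968, although the test written for depth in advance came out on its side: over all mesenchyme-like cells, the bone markers stood only 1.13 times higher in replicate 3 than in replicate 1 (Alpl 1.07, Runx2 1.13, Sp7 1.87). That value also leaves open that cells near the edge of cluster 9 may have been assigned differently between libraries, since cluster 5 also carries Alpl and Runx2, and this was not tested. No biological explanation was tested, because the libraries form 1 group.

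Epithelial cluster 20 held 129, 12 and 126 cells in replicates 1, 2 and 3, or 12.6%, 1.97% and 16.1% of the epithelium. Without centring the highest share was 7.98 times the lowest (12.7%, 1.98% and 15.8%), and with the same doublet rule in every library 7.54 times (12.1%, 2.15% and 16.2%), which argues against both as the whole source. The median UMI counts of epithelium-like cells were 12391, 12415 and 12312, a ratio of 0.995, so a gap in depth is absent, although another test, written in advance, came out on the side of depth. How much of this cluster each dissection took in may differ, and this was not tested.

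The 6 sums of each of the 18 comparisons allow 10 splits into 3 and 3, too few for a share under 0.05. The real split alone reached its own count in each comparison (1 of 10 splits), with real counts of 1864 to 8860 called genes and 0 as the highest count of any other split in edgeR. The classes were drawn from expression in the same cells, so every other split mixes unlike sums and a low count there could be foreseen. No conclusion is drawn from the splits.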
